A study of Rattus norvegicus with 12 samples.

How the data were processed

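RNA was measured in 12 libraries of primary heart cells from Sprague Dawley rats aged 2 days. Per the labels' protocols, hearts were dissociated with an enzymatic kit, a Percoll gradient separated myocytes from fibroblasts, and cells were kept in DMEM with 15% fetal bovine serum and antibiotics. A mix of 2 siRNAs against Yap (25 nM each), or a universal negative control siRNA, was given 16 h after plating, and RNA was taken in Trizol 48 h after transfection. Poly-A RNA was sequenced by a low-input protocol on the BGISEQ-500. The submitters' processing notes name HISAT, Bowtie2 and the rn6 genome. Their versions, the quantification tool, the gene annotation and the number of reads per library are not given in the sources used here.

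The deposited table holds 1 column per library and 14636 genes, and its values are FPKM per the file headers. The table gives no read counts, so the sequencing depth is unknown and no counting error can be given. FPKM summed to between 563193.5 and 620119.3 per library. The spacing of low FPKM values over 1367 low genes gave a relative depth of 0.942 to 1.045 across libraries; 38.6% of 4805 values lay within 0.1 read of a whole multiple, against 20% without such steps. Only values close to a gene's lowest value above 0 were taken as 1 read, which by itself keeps these estimates close together. The spacing therefore shows neither how similar the depths were nor how large. Symbols were blank or turned into dates in 31 lines of the table; 29 of them were restored by gene ID, and 2 could not be. Gene IDs matched a reference table of names in 14516 genes (99.2%). That reference is built on another assembly, so no positions are given. Genes at 0 in every library numbered 208, no pair of libraries was identical, and the table lists 0 mitochondrially encoded genes.

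Values were analysed as log2(FPKM + 1), which understates fold changes of low genes. Genes with a mean of at least 0.5 FPKM over the 12 libraries were tested, which left 11302. All 4 groups of 3 libraries (CM_neg and CM_yap for cardiomyocytes, CF_neg and CF_yap for cardiac fibroblasts, with control or Yap siRNA) were fitted together in limma 3.58.1 (lmFit, then eBayes with a variance trend) under R 4.3.3. The tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 4 comparisons were Yap against control siRNA in each cell type, the difference between these effects (cardiomyocytes minus fibroblasts), and cardiomyocytes against fibroblasts under control siRNA. An exact permutation test of 3 libraries against 3 has 10 splits and cannot give a p below 0.1, so single genes rest on limma's pooled spread. The labels do not say whether the libraries of a group came from separate animals, litters or cultures, so the p-values measure the spread between these libraries alone, which may be technical. Values without a unit beside a gene are log2 fold changes, given with limma's standard error (SE) after the sign ±, and FPKM are given as mean ± SD over 3 libraries. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.

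The comparisons, the test, 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera from limma, which compares a list's genes with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it; fry tests whether a list's genes move, on balance, in 1 direction, and compares them with no other genes. Genes were named under 3 rules. The first covers Yap1, Wwtr1, the Tead genes and the YAP and TEAD target list. The second takes the 10 largest rises and 10 largest falls per comparison among called genes with at least 5 FPKM in the higher group, groups that do not overlap and a proper symbol, or 5 each way for the difference between cell types. The third takes up to 4 members per described list with the smallest p in the list's direction. List members that moved against their list, and markers of other cell types, were named in addition after their values were seen. Some genes that these rules take are not reported here, though they were kept in the tests of genes and lists. Members missing from the table or under the filter, Tead4 among them, were not analysed here.

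Alternatives were other pseudocounts (0.1 and 5), no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, no variance trend, replicate number as a block, only the groups compared in the fit, a limit of 1 on the absolute log2 fold change, an estimated correlation, and leaving out each library in turn. A test on GO process terms given in the deposited table was added after seeing the data, as were counts of list members under each scaling. The fit was also tested on simulated data made from each gene’s own spread, with noise independent between genes and with 80 genes changed by 0.5, 80 by 1 and 40 by 2 on the log2 scale. At a log2 change of 0.5 it recovered 70% of changed genes in cardiomyocytes and 77.5% in fibroblasts. It recovered 42.5% for the difference between cell types and 67.5% between cell types under control siRNA. Changed genes were few beside the 3495 to 7726 called in the data, which makes the adjusted threshold stricter in the simulation. The simulated recovery is therefore not that of the data, where small differences can still be missed. At a log2 change of 1 it recovered 96.2% of changed genes in cardiomyocytes (11127 genes simulated), 100% in fibroblasts (11129 genes), 88.8% for the difference between cell types (11123 genes) and 100% between cell types under control siRNA (11119 genes). Of the calls, 3.9%, 5.7%, 3.3% and 5.4% were false in that order. Among 100 simulated lists without change, camera called 0, 0, 0 and 1. Genes of these lists had independent noise, while the estimated correlation was 0.437 for G2 and M phase genes and 0.559 for ribosomal protein genes. The simulated lists therefore do not show how often camera calls real lists falsely.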

Results

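Poly-A RNA of neonatal rat cardiomyocytes and cardiac fibroblasts was sequenced 48 h after transfection with siRNA against Yap, the transcriptional coactivator at the end of the Hippo pathway, or with a universal negative control siRNA. Each of the 4 groups held 3 libraries. FPKM totals lay between 563193.5 and 620119.3 per library, and the read depth is unknown. Libraries of a group resembled each other closely, with Spearman correlations across genes of 0.990 to 0.996. Between libraries with Yap and control siRNA these correlations had a mean of 0.965 in cardiomyocytes and 0.979 in fibroblasts. Between the cell types under control siRNA their mean was 0.842. The first principal component held 84.5% of the variance and the second 7.5%. Nppa, the atrial natriuretic peptide gene, was the most abundant gene in control cardiomyocytes (9494.8 ± 298.4 FPKM, SD, n = 3).

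The first question was how far the siRNA lowered its target. In cardiomyocytes, Yap1 stood at 55.26, 60.8 and 63.11 FPKM with control siRNA and at 5.9, 4.43 and 6 FPKM with Yap siRNA. Of the mean, 9.1% remained (log2 fold change −3.24 ± 0.10 SE, adjusted p = 1.28e-11). In fibroblasts it stood at 35.42, 37.39 and 33.45 FPKM against 4.45, 3.88 and 4.49 FPKM. There 12.1% remained (−2.79 ± 0.10, adjusted p = 5.81e-11). The difference between these effects was −0.46 ± 0.14 (adjusted p = 0.0215). That call ended under median-of-ratios scaling (−0.32, adjusted p = 0.083), under quantile normalization (−0.27, adjusted p = 0.123) and with a pseudocount of 0.1 (−0.42, adjusted p = 0.0555). It also ended without CF_neg 3 (adjusted p = 0.0552) or CF_yap 3 (adjusted p = 0.0502). Wwtr1, which encodes the Yap paralog TAZ, fell in cardiomyocytes to 65.1% of control (40.3 ± 1.40 to 26.2 ± 1.93 FPKM, SD, n = 3; adjusted p = 4.13e-05). In fibroblasts it had a log2 fold change of −0.15 ± 0.09 (adjusted p = 0.21), and the effects differed (−0.45 ± 0.12, adjusted p = 0.00948). Among the genes of the TEAD factors, through which Yap binds DNA, Tead1 fell in cardiomyocytes (−0.90 ± 0.15, adjusted p = 0.000208) and Tead3 rose (0.35 ± 0.07, adjusted p = 0.00119), while Tead2 did not pass in either cell type (adjusted p = 0.642 and 0.0906). In fibroblasts Tead1 stood at −0.23 (adjusted p = 0.28, or 0.0432 with only the fibroblast groups in the fit) and Tead3 at −0.03. The difference passed for Tead3 (0.38, adjusted p = 0.0117) and for Tead1 (−0.67, adjusted p = 0.0268). Tead2 was called lower in fibroblasts under median-of-ratios scaling (−0.25, adjusted p = 0.0326), quantile normalization (−0.26, adjusted p = 0.0254) and without CF_yap 2 (adjusted p = 0.0319). Its difference between cell types (0.25, adjusted p = 0.119) passed in the same settings (adjusted p = 0.0229, 0.0261 and 0.045). The Tead1 difference was lost under median-of-ratios scaling (adjusted p = 0.079), quantile normalization (adjusted p = 0.0621) and without a filter (adjusted p = 0.0568). It was lost too without CM_neg 2 (adjusted p = 0.0715), CM_neg 3 (adjusted p = 0.0635), CM_yap 1 (adjusted p = 0.0573), CF_neg 3 (adjusted p = 0.0653) or CF_yap 3 (adjusted p = 0.0675).

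Published YAP and TEAD target genes fell as a list in both cell types by camera with its preset correlation, though not with an estimated one (adjusted p = 0.289 and 0.15). Of 18 tested in cardiomyocytes, 15 fell and 2 rose, Asap1 (0.28) and Nt5e (0.73). The counts adjusted over the list alone were 15 and 2 as well (list median −0.52, camera adjusted p = 9.84e-05). Ctgf, which encodes a matrix-associated growth regulator, went from 690.8 ± 92.1 to 255.0 ± 22.9 FPKM (SD, n = 3; log2 −1.43 ± 0.09 SE) and Tgfb2 from 96.3 to 29.7 FPKM (−1.66 ± 0.09). Lats2 and Amotl2, negative regulators of Yap, fell by 1.12 and 1.01 on the log2 scale. In fibroblasts 8 of 18 fell, among them Tgfb2 (−1.70 ± 0.09), Ctgf (1046.1 ± 39.4 to 446.2 ± 9.0 FPKM, −1.23 ± 0.09), Ankrd1 (−0.99 ± 0.08) and Cyr61 (−0.66). Igfbp3, an IGF-binding protein gene, rose (389 to 814 FPKM, 1.07 ± 0.15), as did Nt5e (0.45). The counts adjusted over the list alone were 10 fallen and 3 risen (list median −0.26, camera adjusted p = 2.26e-05). In the difference between cell types, 1 target was higher and 8 were lower in cardiomyocytes (list median −0.34, against −0.132 for all genes). Camera, which compares the list with other genes, did not call it (adjusted p = 0.314), while fry, which tests the list against no change, called it lower (adjusted p = 0.0193). Among single members, Amotl2 fell more in cardiomyocytes (difference −0.84 ± 0.09, adjusted p = 9.24e-06) and Ankrd1 fell more in fibroblasts (0.73 ± 0.11, adjusted p = 0.000237). The smaller fall of Ankrd1 in cardiomyocytes (−0.27 ± 0.08, adjusted p = 0.0127) was not called under median-of-ratios scaling (−0.19, adjusted p = 0.0966) or with only the cardiomyocyte groups in the fit (adjusted p = 0.0756). The calls for Asap1 in cardiomyocytes were lost without CM_neg 1 (adjusted p = 0.0781), CM_neg 3 (adjusted p = 0.062) or CM_yap 2 (adjusted p = 0.0997) and in that smaller fit (adjusted p = 0.0613). Nt5e in fibroblasts was not called under quantile normalization (adjusted p = 0.0611) or without CF_neg 2 (adjusted p = 0.062).

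**Figure D1:**
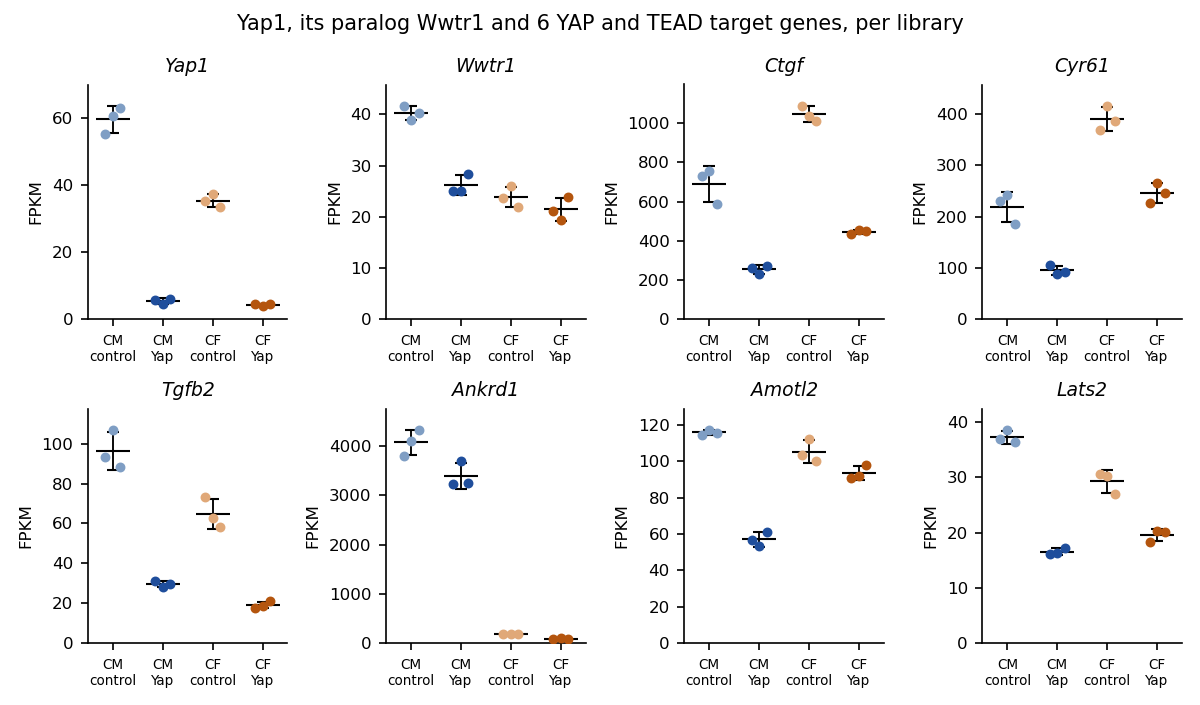
FPKM of Yap1, Wwtr1 and 6 YAP and TEAD target genes in the 4 groups, with a point per library and bars for the mean ± SD (n = 3). Yap1 lies between 4.43 and 6 FPKM in the 3 CM_yap libraries, and Ctgf falls from a mean of 690.8 to 255.0 FPKM in cardiomyocytes and from 1046.1 to 446.2 FPKM in fibroblasts.

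In cardiomyocytes, Yap siRNA was followed by higher levels of contractile and fatty acid oxidation genes and by lower levels of fetal and stress-responsive cardiac, cell cycle and cholesterol synthesis genes. None of these list calls held with an estimated correlation (adjusted p = 0.289 to 0.311), and a separate list of 27 fetal-predominant genes did not pass (11 lower and 6 higher, camera adjusted p = 0.386). Myh6, the gene of the fast alpha myosin heavy chain, rose from 2430.8 ± 341.0 to 5514.5 ± 683.0 FPKM (SD, n = 3; log2 1.18 ± 0.10 SE). Myh7, the gene of the slow beta chain, fell from 2305.5 ± 206.4 to 871.8 ± 68.1 FPKM (−1.40 ± 0.09). Cardiac troponin I (Tnni3) rose from 1760.3 ± 81.4 to 4115.5 ± 616.6 FPKM and myoglobin (Mb) from 126 to 531 FPKM (2.08 ± 0.11). Smooth muscle actin (Acta2) fell from 2353.1 ± 100.6 to 426.5 ± 25.4 FPKM (−2.46 ± 0.07, adjusted p = 4.25e-12). In all, 5626 of 11302 genes were called, 2378 higher (42.3%) and 3248 lower. Of these, 449 had an absolute log2 change of at least 1 (259 higher, 190 lower). The share of called genes that were higher was 53% under median-of-ratios scaling and 47.8% under quantile normalization, so the balance of directions is not fixed.

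Of 26 contractile and calcium-handling genes, 20 rose and 3 fell, with the same counts adjusted over the list alone (median 0.57, camera adjusted p = 7.83e-08, adjusted p = 0.311 with an estimated correlation). The atrial light chain gene Myl7 rose (68.2 to 285 FPKM, 2.04 ± 0.14). Against the list, and named after their values were seen, Actc1 (−0.60), Csrp3 (−0.60) and Actn2 (−0.33) fell. Among 11 fetal and stress-responsive cardiac genes, 8 fell and 2 rose, or 9 and 2 adjusted over the list alone (median −0.98, camera adjusted p = 0.00594, adjusted p = 0.289 with an estimated correlation). Skeletal actin (Acta1) fell from 535 to 132 FPKM (−2.02 ± 0.15) and the LIM-domain gene Fhl1 from 609 to 156 FPKM (−1.96 ± 0.09). Xirp2 (0.98) and Myh7b (1.76) rose, again named after their values were seen. Lpl and Angptl4, which act on lipoproteins outside the cell, fell, while 17 of 24 fatty acid oxidation and uptake genes rose, or 19 risen and 2 fallen adjusted over the list alone (median 0.54, camera adjusted p = 1.93e-07, adjusted p = 0.289 with an estimated correlation). Acsl1, which activates long-chain fatty acids, went from 38.0 to 100 FPKM (1.38 ± 0.08), and Hadh (1.32 ± 0.11) and Etfdh (1.06 ± 0.07) rose too. Nuclear-encoded oxidative phosphorylation genes rose in 11 of 28 cases and fell in 0 (median 0.13, camera adjusted p = 0.00156, adjusted p = 0.499 with an estimated correlation). Ndufa4 changed by 0.73 and Cox6a2 at 0.63. Quantile normalization ended that list's call (11 risen and 2 fallen, median 0.07, adjusted p = 0.12), and median-of-ratios scaling gave 16 risen and 0 fallen.

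**Figure D2:**
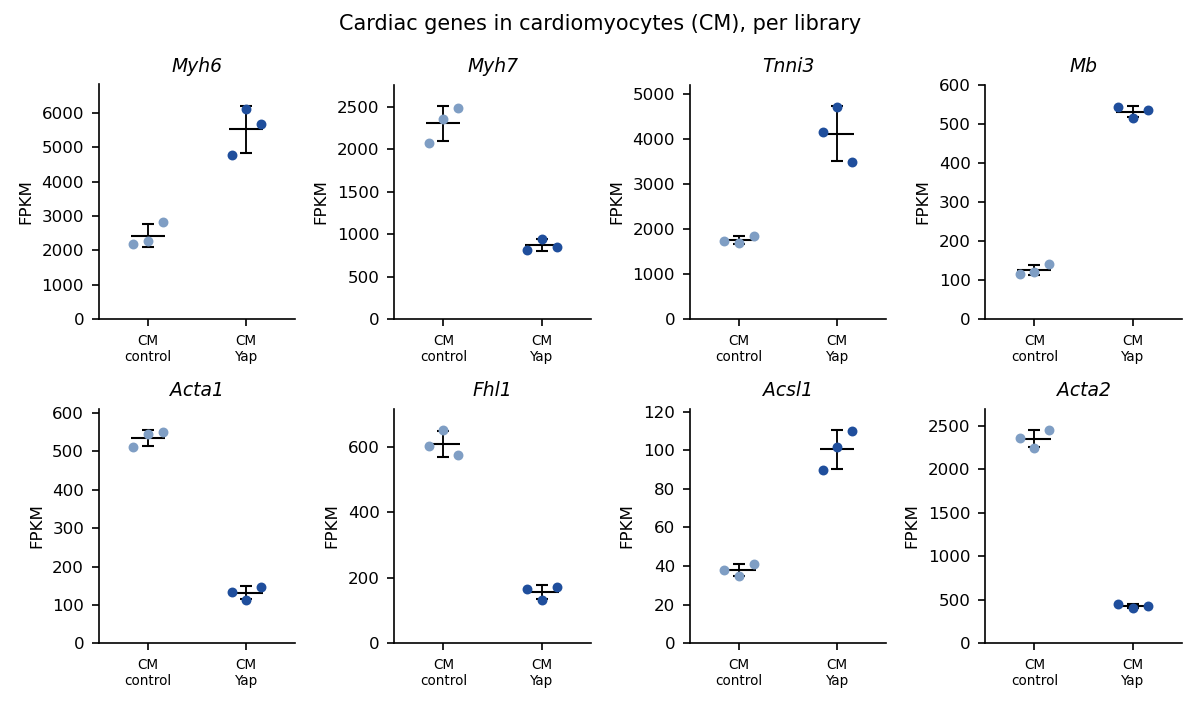
FPKM of 8 contractile, fetal, metabolic and smooth muscle genes in the cardiomyocyte groups, with a point per library and bars for the mean ± SD (n = 3). Myh6 rises from a mean of 2430.8 to 5514.5 FPKM, Myh7 falls from 2305.5 to 871.8 FPKM, and Acta2 falls from 2353.1 to 426.5 FPKM.

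Cell cycle genes fell almost without exception in the cardiomyocyte cultures. These cultures also expressed endothelial markers, of which 7 of 15 fell and 1 rose. Which cells expressed the cell cycle genes was not tested. All 24 G2 and M phase genes tested fell (median −0.62, camera adjusted p = 1.6e-09, adjusted p = 0.289 with an estimated correlation). The mitotic kinase gene Cdk1 stood at 72.4 and 33.1 FPKM (−1.11 ± 0.06) and the mitotic motor gene Kif11 at −0.96. Of 25 S phase genes, 22 fell and Gins2 rose (0.52), or 23 and 1 adjusted over the list alone (median −0.72, camera adjusted p = 6.25e-09, adjusted p = 0.289 with an estimated correlation). Rrm2, a subunit of the enzyme that makes deoxynucleotides, fell from 107 to 36.2 FPKM (−1.55 ± 0.09), and the replicative helicase gene Mcm5 by 1.23 on the log2 scale. Cholesterol synthesis genes fell in 19 of 21 cases (median −0.73, camera adjusted p = 3.08e-08, adjusted p = 0.289 with an estimated correlation), including Idi1 (−1.13 ± 0.08). Of 19 actin cytoskeleton and SRF target genes, 11 fell, with 1 risen and 11 fallen adjusted over the list alone (median −0.42, camera adjusted p = 0.00588, adjusted p = 0.427 with an estimated correlation). None rose as deposited, and 4 rose under median-of-ratios scaling. Among the fallen genes were the focal adhesion genes Vcl (150 to 86.9 FPKM, −0.78) and Zyx (−0.69). Hippo pathway component genes fell in 13 of 20 cases and rose in 3, or 14 and 3 adjusted over the list alone (median −0.39, camera adjusted p = 0.00596, adjusted p = 0.427 with an estimated correlation).

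Inflammatory cytokine and chemokine genes fell in 19 of 25 cases and rose in 1, or 20 and 1 adjusted over the list alone (median −0.50, camera adjusted p = 0.000176, adjusted p = 0.427 with an estimated correlation). Lcn2, the lipocalin 2 gene, fell from 403 to 185 FPKM (−1.12 ± 0.11). Cxcl6, a neutrophil-attracting chemokine gene named after its value was seen, rose from 53 to 71.3 FPKM (0.46 ± 0.16, adjusted p = 0.0238). Interferon-stimulated genes fell in 18 of 25 cases and Ifi27 (0.30) rose (median −0.43, camera adjusted p = 2.9e-05, adjusted p = 0.427 with an estimated correlation). The chemokine gene Cxcl10 stood at 429 and 172 FPKM (−1.32 ± 0.10). Endothelial markers moved beside these lists: 7 of 15 fell, among them Pecam1 (88.5 to 59.3 FPKM, −0.57 ± 0.11) and Eng (279 to 163 FPKM, −0.78 ± 0.10). Kdr rose (0.34, adjusted p = 0.0104), and as a list these markers did not pass (median −0.29, camera adjusted p = 0.0606). The list passed with a pseudocount of 5 (adjusted p = 0.0184), no filter (adjusted p = 0.0442) or median-of-ratios scaling (adjusted p = 0.0476). It also passed with only the cardiomyocyte groups in the fit (adjusted p = 0.0182) and without CM_neg 3 (adjusted p = 0.0288) or CM_yap 1 (adjusted p = 0.0391). Leukocyte markers fell in 7 of 16 cases and rose in 3 (camera adjusted p = 0.443). TGF-beta pathway genes fell in 11 of 22 cases and rose in 2 (median −0.23, camera adjusted p = 0.01, adjusted p = 0.479 with an estimated correlation). The ligand gene Tgfb3 stood at 79.5 and 20.9 FPKM (−1.90 ± 0.10). Smooth muscle and pericyte markers rose in 8 of 12 cases and fell in 2 (median 0.45, camera adjusted p = 0.00714, adjusted p = 0.309 with an estimated correlation). That list shares Pln with the contractile list. It shares Myh11, Des and Lmod1 with the myofibroblast list, which was not called (camera adjusted p = 0.975). Its rise therefore does not by itself show more smooth muscle cells or pericytes. The potassium channel regulator gene Abcc9 changed by 1.65 ± 0.13. Fry gave the same direction as camera for each list called by camera in cardiomyocytes, and none of these calls held with an estimated correlation.

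Among the largest single rises in cardiomyocytes were Igfbp5 (1.4 to 36.7 FPKM, 4.04 ± 0.22), Reg3b (20.6 to 168 FPKM, 2.96 ± 0.13), the heart-restricted gene Lrrc10 (19 to 118 FPKM, 2.57 ± 0.14) and Pla2g2a (17.7 to 108 FPKM, 2.54 ± 0.15). Sphkap (5.56 to 34.4 FPKM), Dhrs7c (4.23 to 24.8 FPKM), Lpar2 (1.32 to 10.6 FPKM) and the hepcidin gene Hamp (62.6 to 291 FPKM) rose as well. The largest falls besides Yap1 and Acta2 were in the skeletal calcium channel gene Cacna1s (6.09 to 0.137 FPKM, −2.64 ± 0.12), Tril (−2.54), the keratin gene Krt18 (13.4 to 1.71 FPKM, −2.46 ± 0.20) and Fgfr2 (11 to 1.42 FPKM, −2.32). Next came the muscle acetylcholine receptor gene Chrna1 (−2.16) and the glutamate transporter gene Slc1a3 (38.3 to 7.85 FPKM, −2.15). Myl6l was listed at 0 in CM_neg, and its values in CM_yap were 211.9, 519.32 and 249.63 FPKM. The sum of Myl6 and Myl6l changed by 0.05 on the log2 scale. The rule also took Rpl37a (251 to 46.9 FPKM, −2.36 ± 0.18), a ribosomal protein gene with many near-identical copies. It took the microRNA entries Mir6328 (−2.72 ± 0.49) and Mir3074 (2.44 ± 0.41) too, which a library of this kind measures poorly. Short ribosomal RNA entries stood higher in CM_yap, with Rn5s at 3.44 and 32.6 FPKM and Rn5-8s at 9.44 and 61.8 FPKM. The long entries Rn18s (−0.39, adjusted p = 0.211) and Rn28s (−0.23, adjusted p = 0.44) did not pass.

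The other lists were not called in cardiomyocytes. Camera's adjusted p was 0.907 for fibrillar matrix (6 genes higher, 7 lower of 26), 0.443 for basement membrane (2 and 5 of 9) and 0.715 for matrix proteases (2 and 5 of 17). For glycolysis it was 0.297 (3 and 9 of 19; called under quantile normalization, adjusted p = 0.0258), and 0.794 for p53 targets (5 and 5 of 19). The unfolded protein and amino acid stress response had 0.147 (5 and 13 of 24). It was 0.896 for NRF2 targets (5 and 7 of 20), 0.443 for fibroblast markers (4 and 2 of 16), 0.122 for epicardial markers (1 and 5 of 9) and 0.794 for Schwann and neuronal markers (1 and 1 of 8). Erythroid markers (0 and 4 of 6, adjusted p = 0.117) and cytosolic ribosomal proteins (12 and 6 of 30, adjusted p = 0.0818) did not pass either. The former passed without CM_yap 1 (adjusted p = 0.0339) and the latter without CM_neg 1 (adjusted p = 0.0269) or CM_yap 3 (adjusted p = 0.0139) and under median-of-ratios scaling (adjusted p = 0.0476). The ribosomal median was 0.07 and turned to −0.07 under quantile normalization (7 higher and 11 lower). The myofibroblast and smooth muscle list (5 and 4 of 14, adjusted p = 0.975) had a median of 0.02 and a mean of −0.16, since Acta2 and Tagln fell far while other members rose. Fry called 8 of the 15 lists that camera did not call in cardiomyocytes, all of them lower, the myofibroblast list included (adjusted p = 0.000148).

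In fibroblasts, Yap siRNA was followed by a rise of inflammatory and interferon-stimulated genes and a fall of smooth muscle contractile, cell cycle and amino acid stress response genes. Of these lists, the smooth muscle contractile and amino acid stress lists were called with an estimated correlation too (adjusted p = 0.0447 each), and the others were not (adjusted p = 0.0706 to 0.282). Pla2g2a, which encodes a secreted phospholipase, rose from 125.3 ± 28.3 to 3590.0 ± 363.7 FPKM (SD, n = 3; log2 4.85 ± 0.15 SE, adjusted p = 8.75e-12). The complement gene C3 rose from 4.07 to 59.4 FPKM (3.58 ± 0.11), complement factor B (Cfb) from 55.5 to 344 FPKM (2.63) and Cxcl6 from 2.21 to 45.1 FPKM (3.84 ± 0.16). Acta2 fell from 3202.2 ± 39.8 to 1615.4 ± 45.1 FPKM (−0.99 ± 0.07). In all, 3495 of 11302 genes were called, 2311 higher (66.1%) and 1184 lower. Of these, 261 had an absolute log2 change of at least 1 (229 higher, 32 lower). The higher share was 54.8% under median-of-ratios scaling and 46.3% under quantile normalization.

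Of 25 inflammatory cytokine and chemokine genes, 20 rose and 0 fell, or 21 and 1 adjusted over the list alone (median 0.94, camera adjusted p = 8.19e-13, adjusted p = 0.12 with an estimated correlation). Lcn2 went from 118 to 596 FPKM (2.33 ± 0.11), the adhesion molecule gene Vcam1 from 12.9 to 65.1 FPKM (2.26 ± 0.12). Nfkbia, the NF-kappaB inhibitor gene that NF-kappaB itself induces, went from 42.8 to 89.2 FPKM (1.04 ± 0.07). Interferon-stimulated genes rose in 22 of 25 cases (median 0.43, camera adjusted p = 1.14e-07, adjusted p = 0.282 with an estimated correlation). The antiviral gene Rsad2 (18.7 to 41.7 FPKM, 1.12) and the transcription factor gene Irf7 (0.49) were among them. Beside them, 2 of 16 leukocyte markers rose, the macrophage gene Adgre1 (3.38 to 7.66 FPKM, 0.98 ± 0.13) and Mrc1 (0.32, adjusted p = 0.029). The leukocyte list did not pass (median 0.13, camera adjusted p = 0.498). The Mrc1 call was lost under both scalings (adjusted p = 0.0576 and 0.145). It was lost as well without CF_neg 1 (adjusted p = 0.0724), CF_neg 2 (adjusted p = 0.0524), CF_neg 3 (adjusted p = 0.0916), CF_yap 1 (adjusted p = 0.0882) or CF_yap 2 (adjusted p = 0.0884). Further large rises were in the autotaxin gene Enpp2 (2.18 to 43.1 FPKM, 3.79 ± 0.11), the protease inhibitor gene Slpi (4.59 to 61.9 FPKM, 3.49 ± 0.11) and Chi3l1 (7.40 to 89.9 FPKM, 3.45). Csf2rb (2.75) and C6 (2.71) rose as well.

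Myofibroblast and smooth muscle contractile genes fell in 10 of 14 cases and rose in 3, Myh11, Synpo2 and Des (median −0.55, camera adjusted p = 2.03e-05). This call held with adjusted p = 0.0447 with an estimated correlation. Tagln, an actin-binding gene of smooth muscle, fell from 2849.5 ± 119.0 to 1603.5 ± 59.0 FPKM (−0.83) and calponin 1 (Cnn1) by 0.59 on the log2 scale. Actin cytoskeleton and SRF target genes fell in 14 of 19 cases (median −0.35, camera adjusted p = 1.33e-08, adjusted p = 0.109 with an estimated correlation). Vcl changed by −0.82 and Srf itself at −0.49. Of 24 genes of the unfolded protein and amino acid stress response, 15 fell, or 19 adjusted over the list alone (median −0.43, camera adjusted p = 1.34e-14). This call held too, with adjusted p = 0.0447 with an estimated correlation. Chac1, a glutathione-degrading enzyme gene, went from 41.5 to 17.8 FPKM (−1.18 ± 0.09), and Trib3 (−1.02), the serine synthesis gene Phgdh (−0.71) and Mthfd2 (−0.79) fell too. Genes of G2 and M phase fell in 22 of 24 cases, or 23 adjusted over the list alone (median −0.43, camera adjusted p = 2.64e-14, adjusted p = 0.12 with an estimated correlation). Cdk1 changed by −0.76. S phase genes fell in 21 of 25 cases, or 23 with 1 risen adjusted over the list alone (median −0.46, camera adjusted p = 3.71e-13, adjusted p = 0.0706 with an estimated correlation). Mcm5 changed by −0.65.

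Cholesterol synthesis genes fell in 11 of 21 cases (median −0.26, camera adjusted p = 6.19e-07, adjusted p = 0.209 with an estimated correlation). Fatty acid oxidation and uptake genes rose in 13 of 24 cases and fell in 3, or 14 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.00323, adjusted p = 0.513 with an estimated correlation). The PPAR target gene Angptl4 changed by 1.27 ± 0.12 and the carnitine transferase gene Cpt1a at 0.72. Fetal and stress-responsive cardiac genes fell in 5 of 11 cases and rose in 1, or 7 and 2 adjusted over the list alone (median −0.37, camera adjusted p = 0.00126, adjusted p = 0.0706 with an estimated correlation). Acta1 stood at 5.93 and 1.84 FPKM. Hippo pathway component genes fell in 3 of 20 cases and rose in 1, or 2 and 1 adjusted over the list alone (median −0.09, camera adjusted p = 0.0241, adjusted p = 0.513 with an estimated correlation). The number fallen was 5 under median-of-ratios scaling and 8 under quantile normalization (median −0.17). The Hippo call was lost with a filter of 5 FPKM (adjusted p = 0.0509) and without CF_neg 2 (adjusted p = 0.062) or CF_yap 2 (adjusted p = 0.0562). Oxidative phosphorylation genes fell in 6 of 28 cases and Cox6a2 rose, or 6 and 0 adjusted over the list alone (median −0.08, camera adjusted p = 0.00887, adjusted p = 0.705 with an estimated correlation). Quantile normalization (adjusted p = 0.104) or leaving out CF_neg 3 (adjusted p = 0.0892) ended the call, and fry gave an adjusted p of 0.196. The ribosomal protein list was called (median −0.06, camera adjusted p = 0.033, adjusted p = 0.8 with an estimated correlation), although 0 of its 30 genes passed by limma, 0 also at an unadjusted p under 0.05, and fry did not call it (adjusted p = 0.483). That call ended with a filter of 5 FPKM (adjusted p = 0.0679) and without CF_neg 3 (adjusted p = 0.228), CF_yap 1 (adjusted p = 0.0937) or CF_yap 3 (adjusted p = 0.197). Under quantile normalization the median was 0 (adjusted p = 0.998).

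The largest falls besides Yap1 and Tgfb2 were in the Notch target gene Heyl (17.5 to 4.31 FPKM, −1.79 ± 0.11), the interleukin 33 receptor gene Il1rl1 (155 to 48.6 FPKM, −1.65) and the receptor gene Notch3 (37.4 to 11.9 FPKM, −1.57 ± 0.15). Cth (24.6 to 7.71 FPKM, −1.55), Tgfb3 (166 to 57.2 FPKM, −1.52), Megf6 (−1.42) and the collagen receptor gene Itga11 (32.5 to 12.6 FPKM, −1.31) followed. TGF-beta pathway genes fell in 9 of 22 cases and rose in 6, or 11 and 8 adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.0719, or 0.0481 without CF_neg 3). Fibroblast markers (7 rose and 2 fell of 16, camera adjusted p = 0.156) did not pass as a list, except under quantile normalization (adjusted p = 0.0129) and with a pseudocount of 5 (adjusted p = 0.0458). Yet Pdgfra rose from 29.7 to 102 FPKM (1.75 ± 0.09) and the proteoglycan gene Dcn from 177 to 588 FPKM (1.73 ± 0.12). Fibrillar matrix genes went both ways (8 rose and 6 fell of 26, camera adjusted p = 0.809, median −0.02 and mean 0.17). Contractile cardiac genes (12 rose and 4 fell of 26, or 8 and 4 under quantile normalization, camera adjusted p = 0.262) were not called. Matrix proteases (9 and 2 of 17, 0.103, or 0.0198 under quantile normalization), endothelial markers (4 and 1 of 15, 0.246) and smooth muscle and pericyte markers (6 and 4 of 12, 0.991) did not pass either. Fry called 7 of the 15 lists that camera did not call in fibroblasts, all of them higher.

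The responses of the cell types were compared directly. Inflammatory and interferon-stimulated genes moved apart, list calls that did not hold with an estimated correlation (adjusted p = 0.384 each). C3 rose in fibroblasts and fell in cardiomyocytes (42.2 to 23.4 FPKM, −0.83). The difference was −4.41 ± 0.15 SE (n = 3 per group, limma adjusted p = 1.23e-10), and Slpi did likewise (−4.34 ± 0.16). Lcn2 differed by −3.46 ± 0.15, Vcam1 by −2.76 ± 0.18, Rsad2 by −2.04 ± 0.15 and Cxcl10 by −1.92 ± 0.14. In the other direction, Igfbp5 rose in cardiomyocytes and stood at −0.35 in fibroblasts (adjusted p = 0.259; difference 4.39 ± 0.32). Sphkap rose in cardiomyocytes and fell in fibroblasts (−0.48; difference 2.91 ± 0.18). The effect differed in 3993 of 11302 genes, 1320 higher in cardiomyocytes (33.1%) and 2673 lower. Beyond an absolute log2 difference of 1 there were 609 (180 higher, 429 lower). The median of all genes was −0.132 and moved by 0.118 under median-of-ratios scaling and by 0.136 under quantile normalization. These scalings put the higher share at 51.8% and 51.2%, so small differences have no fixed sign.

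Of 25 inflammatory genes, 24 had a lower effect in cardiomyocytes and 0 a higher one, Lif not passing (median difference −1.41, camera adjusted p = 1.55e-14, adjusted p = 0.384 with an estimated correlation). Cxcl6 rose in both cell types, with a difference of −3.38 ± 0.22 on the log2 scale. Interferon-stimulated genes had a lower effect in 23 of 25 cases, or 24 with 1 higher adjusted over the list alone (median −0.83, camera adjusted p = 1.17e-10, adjusted p = 0.384 with an estimated correlation). Oasl differed by −1.97 ± 0.13. Moving with them, 8 of 15 endothelial markers had a lower effect (median −0.48, camera adjusted p = 0.033, adjusted p = 0.592 with an estimated correlation). Pecam1 differed by −1.14 and Eng by −1.04. The endothelial call ended with a pseudocount of 5 (adjusted p = 0.0508) and a filter of 5 FPKM (adjusted p = 0.0943). It also ended without CM_neg 1 (adjusted p = 0.0531), CM_yap 3 (adjusted p = 0.0823) or CF_neg 3 (adjusted p = 0.0531). Leukocyte markers (8 lower and 1 higher of 16) did not pass (camera adjusted p = 0.314). Epicardial markers had a lower effect in 6 of 9 cases, or 7 adjusted over the list alone (median −0.81, camera adjusted p = 0.0113, adjusted p = 0.502 with an estimated correlation). A filter of 5 FPKM ended that call (adjusted p = 0.152).

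**Figure D3:**
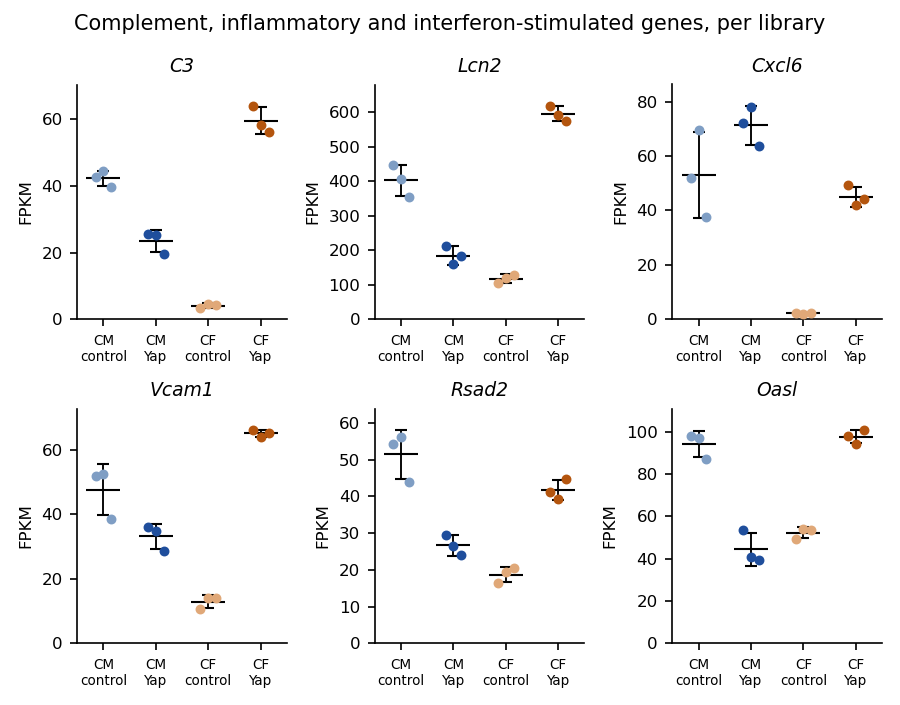
FPKM of 6 inflammatory and interferon-stimulated genes in the 4 groups, with a point per library and bars for the mean ± SD (n = 3). In fibroblasts C3 rises from a mean of 4.07 to 59.4 FPKM and Lcn2 from 118 to 596 FPKM, while in cardiomyocytes they fall from 42.2 to 23.4 FPKM and from 403 to 185 FPKM.

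Contractile cardiac genes had a higher effect in cardiomyocytes in 15 of 26 cases and a lower one in 1, or 16 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 6.47e-07, adjusted p = 0.472 with an estimated correlation). With control siRNA their levels were far higher in cardiomyocytes (median log2 difference 5.55). The effect in fibroblast cultures thus rests on much lower values, and which cells gave them was not tested. Cardiac troponin T (Tnnt2) rose in cardiomyocytes (0.73) and fell in fibroblasts (−0.47), a difference of 1.21 ± 0.13. Oxidative phosphorylation genes had a higher effect in 13 of 28 cases (median 0.26, camera adjusted p = 7.58e-07, adjusted p = 0.472 with an estimated correlation). Atp5o differed by 0.66. Fatty acid oxidation genes were higher in 9 of 24 with 2 lower (median 0.24, camera adjusted p = 0.000608, adjusted p = 0.502 with an estimated correlation). Acsl1 differed by 1.37. The unfolded protein and amino acid stress list was higher in 10 of 24 and lower in 3, or 11 and 3 adjusted over the list alone (median 0.21, camera adjusted p = 7.52e-05, adjusted p = 0.384 with an estimated correlation). The chaperone gene Hspa5 differed by 0.88. Cholesterol synthesis genes were lower in 12 of 21, or 13 adjusted over the list alone (median −0.45, camera adjusted p = 0.00157, adjusted p = 0.539 with an estimated correlation). Myofibroblast and smooth muscle genes were higher in 8 of 14 and lower in 4 (median 0.31, camera adjusted p = 0.033, adjusted p = 0.384 with an estimated correlation), and Acta2 differed by −1.47. This call ended under quantile normalization (adjusted p = 0.171) and without CM_yap 3 (adjusted p = 0.0612). Smooth muscle and pericyte markers were higher in 5 of 12 and lower in 2 (median 0.24, camera adjusted p = 0.0311, adjusted p = 0.472 with an estimated correlation). Notch3 differed by 2.03 ± 0.22. Those markers lost the call with a pseudocount of 5 (adjusted p = 0.0633) and without CM_yap 3 (adjusted p = 0.0612). Ribosomal protein genes were higher in 10 of 30 and lower in 1 (median 0.12, camera adjusted p = 0.00161, adjusted p = 0.667 with an estimated correlation). Their median turned to −0.08 under quantile normalization (4 higher and 5 lower, adjusted p = 0.641), and fry gave an adjusted p of 0.148. The S phase (2 higher and 10 lower of 25, adjusted p = 0.0704) and G2 and M phase lists (0 and 7 of 24, adjusted p = 0.164) were not called. The former passed without CM_neg 3 (adjusted p = 0.0451), CM_yap 1 (adjusted p = 0.0229) or CF_yap 1 (adjusted p = 0.0312) and without a filter (adjusted p = 0.0277). The latter passed without CM_neg 3 (adjusted p = 0.0361). Both scalings left fewer members lower, 7 of the S phase list and 1 of the G2 and M phase list (median −0.08). Of the 17 lists that camera did not call for the difference, fry called 10, all of them lower in cardiomyocytes, the direction in which the median of all genes lay.

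Across the 11302 genes, the effects in the cell types correlated with Spearman's 0.318 (jackknife SE 0.041) and Pearson's 0.276. The comparisons share no library, and genes are not independent replicates. Genes called higher in both numbered 788 (486.2 expected if the calls were independent) and lower in both 736 (340.3 expected). Opposite calls were fewer than that expectation, with 395 lower in cardiomyocytes and higher in fibroblasts (664.1 expected) and 100 the other way (249.1 expected). Calls shared by the cell types were counted on values as deposited only, and other scalings moved the balance of directions in each cell type. All 495 genes with opposite calls also passed the test of the difference. That outcome was fixed by their selection: opposite effects add up in the difference, while its SE is only moderately larger (median 0.144 against 0.102).

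**Figure D4:**
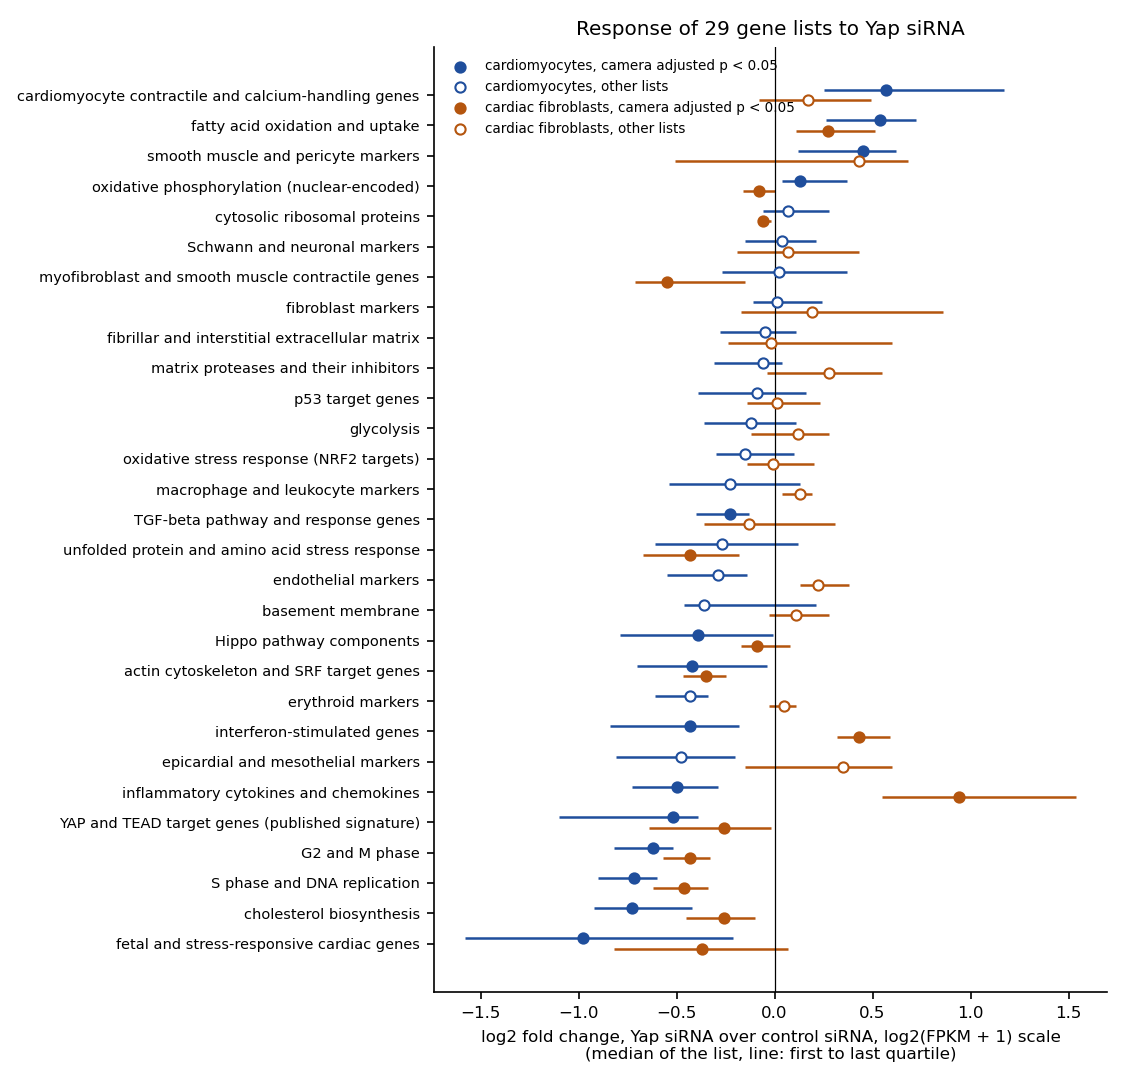
Median log2 fold change of the tested members of each of the 29 gene lists with Yap siRNA in cardiomyocytes and in fibroblasts, with lines from the first to the last quartile and filled points where camera's adjusted p was under 0.05. The inflammatory list lies at −0.50 in cardiomyocytes and 0.94 in fibroblasts, and G2 and M phase genes lie at −0.62 and −0.43.

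Under control siRNA the cell types differed in the genes of their own lineages. Fibroblasts held 378 FPKM of the microfibril gene Mfap4 against 0.597 in cardiomyocytes (log2 −7.91 ± 0.13 SE, n = 3). They held 4029.5 ± 75.2 FPKM of collagen III (Col3a1) against 29.6, and 137 FPKM of the fibroblast transcription factor gene Tcf21 against 1.16. Cardiomyocytes held 1088.8 ± 70.8 FPKM of the muscle LIM protein gene Csrp3 against 12.4 (6.35) and 2430.8 FPKM of Myh6 against 33.3 (6.14). They also held 2838.1 ± 74.6 FPKM of the natriuretic peptide gene Nppb against 43.4 (6.01). Of 11302 genes, 7726 were called, 4744 higher in cardiomyocytes (61.4%) and 2982 lower. An absolute log2 difference of 1 was passed by 2350 (1496 higher, 854 lower). The median of all genes was 0.125 and moved by −0.118 under median-of-ratios scaling and −0.187 under quantile normalization. Under these, 50.8% and 45.0% of calls were higher. Yap1 was higher in cardiomyocytes by 0.74 ± 0.10 on the log2 scale (adjusted p = 8.4e-06), and so was Wwtr1 (0.73).

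All 26 contractile genes were higher in cardiomyocytes (median 5.55, camera adjusted p = 2.03e-18, adjusted p = 0.0631 with an estimated correlation). So were 10 of 11 fetal and stress-responsive cardiac genes (median 4.05, camera adjusted p = 2.52e-07, a call that held with an estimated correlation at adjusted p = 0.025). All 28 oxidative phosphorylation genes (median 1.68, camera adjusted p = 3.8e-13, adjusted p = 0.0875 with an estimated correlation) were higher. So were 23 of 24 fatty acid oxidation genes (median 1.54, adjusted p = 2.61e-08, adjusted p = 0.0949 with an estimated correlation) and 18 of 19 glycolysis genes (median 0.84, adjusted p = 3.43e-06, adjusted p = 0.0668 with an estimated correlation). Fibroblast markers were lower in 16 of 16 cases (median −4.04, camera adjusted p = 1.56e-15, adjusted p = 0.0631 with an estimated correlation). Fibrillar matrix genes were lower in 25 of 26, or 26 adjusted over the list alone (median −3.43, adjusted p = 4.45e-20, adjusted p = 0.0631 with an estimated correlation). Matrix proteases (14 lower and 1 higher of 17, adjusted p = 2.78e-08) and myofibroblast genes (11 lower and 3 higher of 14, adjusted p = 0.00126) were mostly lower, each with adjusted p = 0.0631 with an estimated correlation. Among markers of other cells, those of endothelial and erythroid cells were higher in the cardiomyocyte cultures. All 15 endothelial markers were higher (median 3.33, camera adjusted p = 2.78e-08, adjusted p = 0.0631 with an estimated correlation), Pecam1 at 88.5 against 1.09 FPKM and Cdh5 at 92.7 against 1.43 FPKM. The endothelial and platelet adhesion gene Selp had the largest difference towards cardiomyocytes among named genes with values above 0 in both groups (148 against 0.543 FPKM, 6.59 ± 0.10). Erythroid markers were higher in 5 of 6 cases (camera adjusted p = 0.00171, adjusted p = 0.0949 with an estimated correlation), Hba1 standing at 83.0 FPKM in cardiomyocytes and listed at 0 in fibroblasts. Leukocyte markers (4 higher and 8 lower of 16, median −0.28) were not called by camera (adjusted p = 0.178, or 0.0215 with a filter of 5 FPKM). Neither were smooth muscle and pericyte markers (4 and 7 of 12, median −0.92, adjusted p = 0.21). Schwann and neuronal markers (2 and 4 of 8, median −0.25, adjusted p = 0.301) were called lower without a filter (adjusted p = 0.0456) and by fry (adjusted p = 0.0347).

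Inflammatory genes were higher in cardiomyocyte cultures in 21 of 25 cases and lower in 1, or 21 and 2 adjusted over the list alone (median 1.80, camera adjusted p = 1.11e-05, adjusted p = 0.276 with an estimated correlation). S phase genes were higher in 20 of 25 (median 0.43, adjusted p = 0.00592, adjusted p = 0.408 with an estimated correlation), or in 17 under median-of-ratios scaling (median 0.3). Ribosomal protein genes were lower in 30 of 30 cases (median −0.81, camera adjusted p = 1.11e-12, adjusted p = 0.175 with an estimated correlation). The unfolded protein and amino acid stress list was lower in 18 of 24 with 3 higher, or 18 and 4 adjusted over the list alone (median −0.78, adjusted p = 1.83e-06, adjusted p = 0.0875 with an estimated correlation). Epicardial markers (5 lower and 1 higher of 9, adjusted p = 0.026, adjusted p = 0.408 with an estimated correlation) lost the call under median-of-ratios scaling (adjusted p = 0.0516) and quantile normalization (adjusted p = 0.0625). Actin cytoskeleton genes (9 lower and 4 higher of 19, adjusted p = 0.0329, adjusted p = 0.484 with an estimated correlation) lost it under quantile normalization (adjusted p = 0.148). The YAP and TEAD target list was not called by camera (8 higher and 9 lower of 18, median −0.20, adjusted p = 0.241) but was called lower by fry (adjusted p = 0.00177). The Hippo list was called by neither (adjusted p = 0.985 and 0.063). Of the 12 lists that camera did not call here, fry called 4, 2 higher and 2 lower.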

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

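The tests of scaling, leukocytes, endothelial cells, the share of cardiomyocytes, protein-coding short genes and the Myl6l reads were chosen after the results were seen, while those of all short genes and of other splits of the libraries were written down before their values were known. In 4 results the effects of Yap siRNA were called in opposite directions in the cell types, and their difference was called too. Other lists with a called difference, but without opposite calls, are given above. The median difference, cardiomyocytes minus fibroblasts, was −1.41 for inflammatory cytokine and chemokine genes, −0.83 for interferon-stimulated genes and 0.26 for nuclear-encoded oxidative phosphorylation genes. None of these list differences was called by camera with an estimated correlation (adjusted p = 0.384, 0.384 and 0.472). Quantile normalization also ended the oxidative phosphorylation call within each cell type (camera adjusted p = 0.12 in cardiomyocytes and 0.104 in fibroblasts). In addition, 495 genes were called in opposite directions in the cell types, 395 lower in cardiomyocytes and higher in fibroblasts and 100 the reverse. These genes were counted on values as deposited only. Other scalings moved the balance of directions in each cell type, so the split into 395 and 100 may depend on the scaling. Opposite calls ensure that these genes pass the test of the difference, so for them that test adds no evidence of its own. Of these 4, explanations were weighed for the inflammatory genes alone. For the other lists only the processing was varied, and the median difference was −0.70 and −0.76 for interferon-stimulated genes and 0.39 and 0.24 for oxidative phosphorylation genes under median-of-ratios scaling and quantile normalization. The contractile genes and Myl6l were chosen for weighing after their values were seen, not because of a difference between cell types.

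Inflammatory genes fell in cardiomyocytes and rose in fibroblasts. Scaling of the columns as the whole cause is argued against, since the list's median difference was still −1.32 under median-of-ratios scaling and −1.28 under quantile normalization. More leukocytes in the fibroblast cultures with Yap siRNA would raise leukocyte markers as far as the list, but the list rose by 0.81 more than those markers (median, bootstrap 95% interval 0.45 to 1.4). Fewer endothelial cells in the cardiomyocyte cultures could contribute to the fall there, because the list fell by only 0.21 more than endothelial markers (interval −0.06 to 0.52), and this stays open, although Kdr rose while 7 other markers fell. A response of the fibroblasts and cardiomyocytes themselves to loss of Yap also stays open as a hypothesis. A response to the siRNAs themselves, apart from loss of Yap, was not tested and stays open too. The groups differed in the siRNAs given, a mix against Yap or a universal negative control. No group received another mix against Yap or had Yap restored, so the groups cannot separate these responses. The same limit holds for the other effects of Yap siRNA reported here.

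Contractile genes rose and fetal cardiac genes fell in cardiomyocytes. A larger share of cardiomyocytes in the cultures with Yap siRNA would raise both lists alike, whereas their medians lay 1.55 apart (bootstrap 95% interval 0.65 to 2.39). This gap restates the pattern that prompted the test, and its interval covers genes, not cultures. It goes against a larger share as the only cause. A larger share beside a separate fall of fetal genes stays open. Better recovery of short transcripts would lift short genes as far as the contractile list, yet that list lay 0.57 above the 127 genes with a genomic span under 1 kb (interval 0.35 to 0.95), whose median was 0. Of these genes 50 are microRNA entries, which a poly-A library measures poorly. For the 55 that code for proteins the median was 0.05 and the gap 0.52 (interval 0.29 to 0.95). Some short transcripts did rise in the same libraries, Rn5s by 3.03, Rn5-8s by 2.57 and Atp5i by 1.80 on the log2 scale (490 to 1705 FPKM), while the long Rn18s and Rn28s did not pass. Genomic span is not transcript length, and short transcripts of genes with longer introns lie outside this set. Better recovery of short transcripts therefore stays open, for single genes and for the list. A change of the program within cardiomyocytes is a candidate explanation. One form of it, a shift from fetal towards postnatal expression, was tested on other lists: postnatal genes rose (median 0.55, camera adjusted p = 1.49e-06, a call lost with an estimated correlation at adjusted p = 0.125) and fetal-predominant genes did not pass (adjusted p = 0.386), so it stays open.

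Myl6l was listed at 0 in all libraries but those of cardiomyocytes with Yap siRNA. A likely source is reads shared between Myl6 and Myl6l, near copies of each other, since the sum of both changed by only 0.05 on the log2 scale, from 1166.7 ± 41.2 to 1208.8 ± 9.08 FPKM. What moved the assignment of reads between them in these libraries alone is not known, and Rpl37a, Rn5s and Rn5-8s shifted in the same libraries.

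Other splits of the libraries into groups of 3 were fitted in limma in the same way. For 3 against 3 the 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups, which moves a real effect into the spread. Few calls in the other splits were thus largely fixed in advance and are no evidence of their own. In cardiomyocytes the real split was the 1 split to call 5626 genes, and the highest other called 2 (674 at an unadjusted p under 0.05). In fibroblasts 1 split called 3495, and the highest other called 0 (435 unadjusted), and between the cell types under control siRNA 1 split called 7726, and the highest other called 0 (178 unadjusted). For the difference between cell types, 2 of 100 splits, the real one included, called at least 3993 genes. These splits cannot exclude chance for the difference. Exchanging labels within a cell type also moves the effect of Yap siRNA in that cell type into the difference or the spread. The highest other, with 5609 genes, exchanged the labels of all fibroblast libraries and so tested the sum of both effects, a real structure of the samples; the next highest called 2928.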

How the results depend on the processing

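Limiting calls to an absolute log2 fold change of at least 1 left 449 genes in cardiomyocytes, 261 in fibroblasts, 609 for the difference between cell types and 2350 between cell types under control siRNA, by construction. Under quantile normalization the ribosomal protein list turned to a median of 0 in fibroblasts (adjusted p = 0.998) and to −0.08 for the difference (adjusted p = 0.641); the cause was not tested. The other 62 main values under alternatives stayed within 1.5 times the reported value, and the Yap1 changes and the correlation kept their sign. For called genes only the total was compared. The majority direction of those calls turned under scaling in each comparison, in fibroblasts from 66.1% to 46.3% higher under quantile normalization. Leaving out each library in turn gave 4864 to 5460 called genes in cardiomyocytes, 2634 to 2976 in fibroblasts, 3356 to 4135 for the difference and 7211 to 7328 between cell types, log2 fold changes of Yap1 of −3.31 to −3.13 and −2.83 to −2.73, and correlations between the effects of 0.285 to 0.332. Of list results under other settings, 1048 kept their direction and call, 15 gained a call and 66 lost it, most of them with an estimated correlation; of named genes, 4866 kept, 33 gained and 67 lost it. When single libraries were left out, 848 list results kept their call, 11 gained and 11 lost it, against 4163, 16 and 86 for named genes. Replicate numbers were not taken to pair the samples: after removal of group means, libraries of equal number correlated at only 0.14, 0.04 and 0.09 in cardiomyocytes (each best with its own number), 0, −0.09 and −0.12 in fibroblasts and −0.06, 0.05 and −0.06 between cell types. As a block they gave 5565, 3448, 3885 and 7665 calls, and the endothelial list passed in cardiomyocytes (adjusted p = 0.047). A count-based test was not run because the table gives no counts. Without counts, depth limits can be stated only on the FPKM scale: values near 0 carry an unknown counting error, and pseudocount and filter act mainly there.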

Other observations

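The tests on GO process terms and on counts under each scaling were added after the data were seen, and the lists of postnatal and fetal genes were written after the contractile result was seen but before their own values were. Of 397 GO process terms with 15 to 200 tested genes, camera called 3 in cardiomyocytes, 46 in fibroblasts and 20 for the difference between cell types. In fibroblasts, genes of tRNA aminoacylation, which load amino acids onto tRNAs, fell in 18 of 40 cases and rose in 3 (median −0.18, adjusted p = 5.09e-06, adjusted p = 0.0696 with an estimated correlation). Genes of antigen processing and presentation of peptide antigen rose in 14 of 21 cases and fell in 0 (median 0.43, adjusted p = 0.00104, adjusted p = 0.61 with an estimated correlation), and those of the defense response rose in 51 of 114 and fell in 5 (median 0.30, adjusted p = 0.000182, adjusted p = 0.638 with an estimated correlation). RNA transport genes fell in fibroblasts in 15 of 31 cases (median −0.24, adjusted p = 1.19e-05, adjusted p = 0.205 with an estimated correlation) and in cardiomyocytes in 19 of 31 (median −0.35, adjusted p = 0.006, adjusted p = 0.991 with an estimated correlation). For the difference between cell types, leukocyte chemotaxis genes were lower in cardiomyocytes in 11 of 20 cases (median −0.64, adjusted p = 0.016) and ATP biosynthesis genes higher in 9 of 16 (median 0.43, adjusted p = 0.00086), each with adjusted p = 0.992 with an estimated correlation.

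A shift of cardiomyocytes from fetal towards postnatal expression is a hypothesis that the rise of Myh6 and Tnni3 and the fall of Myh7 may suggest. It was tested on a list of 25 genes that rise after birth and a list of 27 fetal-predominant genes, all outside the contractile and fetal lists above, though Tagln, Cnn1 and Myl9 belong to the myofibroblast list fixed before. The postnatal genes rose in 16 cases and fell in 2 (median 0.55, camera adjusted p = 1.49e-06, adjusted p = 0.125 with an estimated correlation). The fetal-predominant genes fell in 11 cases and rose in 6, and did not pass (median −0.19, adjusted p = 0.386). The medians lay 0.74 apart, and neither a rise of postnatal genes that holds with an estimated correlation nor a joint fall of fetal genes was shown, so the hypothesis stays open.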
